A study of Mus musculus with 2 samples.

How the data were processed

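Gene expression was compared between 2 cell populations sorted from mouse dorsal skin by the brightness of a reporter, green fluorescent protein knocked into the Lgr5 gene or into the Lgr6 gene. Lgr5 and Lgr6 encode related receptors for R-spondins. Per the labels' protocols, each sort drew on 3 mice, and 150 ng of Trizol-prepared total RNA went into a linear amplification labelling reaction. The 2 samples are 2 two-colour Agilent arrays of opposite dye orientation. On array 1 the Lgr5-high RNA carried Cy3 and the Lgr6-high RNA Cy5, and on array 2 the dyes were exchanged.

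The authors deposited 1 scanner table per array, with the intensity of each spot and of its local background in both channels on a linear scale. Per the file headers, these intensities were extracted with Agilent Feature Extraction 10.5.1.1, whereas the submitters' processing notes name version 9.5.3, and it stays open which of the 2 is right. The same deposited tables hold the software's own log10 ratio of Cy5 over Cy3, computed after its background subtraction and dye normalisation, and a p-value of that ratio per spot from its error model. Low spots had been replaced by surrogate values, so that the deposited log10 ratio was exactly 0 at 48.6% of probe spots on array 1 and 48.4% on array 2. The authors' value table of the series holds log10 ratios equal to the scanner's on array 1 and to the scanner's with the sign turned on array 2, within rounding. Its direction is therefore Lgr6-high over Lgr5-high on both arrays, the median of each of its columns was 0, and neither its scale nor its direction stays unknown. Probe positions in the files are on mouse build mm9.

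Each array held 45018 spots, of which 43379 were probe spots and 1639 controls. Background was corrected with normexp (offset 50) from the mean spot signal and the median local background. Log ratios were then normalised by loess within each array, with control spots at weight 0. Control spots and spots that the scanner software marked as non-uniform or as population outliers (139 and 204 probe spots on arrays 1 and 2) were left out. No probe spot was saturated. Replicate spots of a probe were averaged, giving 41174 probes, and each ratio was turned to log2 of Lgr6-high over Lgr5-high by the dyes in the labels. Before turning, the scanner's log ratios of Cy5 over Cy3 on the 2 arrays had a Pearson correlation of -0.447 over all probe spots, the sign that exchanged dyes give. The normexp model was fitted on spots without an outlier mark. This departs from the tool's default and was settled after the data were seen, because 1 marked spot with a very bright local background distorted the default fit on array 2. With this spot in, the fitted Cy5 background had an SD of 387, and 2.42 with only this spot left out. The default fit on all spots is among the alternatives, and it gave 124 and 151 called genes in place of 451 and 295. Leaving out only the 1 spot gave 450 and 292.

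A probe entered the comparison if it was well above background in the channel of at least 1 population on both arrays. Each gene was represented by its passing probe with the highest mean log2 intensity. This left 6195 genes, 352 of them transcripts without a gene symbol. Probes were named through their unversioned accessions in a RefSeq gene table of build GRCm38.p6 (25097 probes), then by symbol (6333) or unique synonym (1640). For 1445 probes the name in the file was kept, and 6659 had no name. No coordinate of that table was used. Of 966 genes with several passing probes, 185 met the rule below by at least 1 probe and 120 of these by only some of their probes; none had probes past 2-fold in opposite directions.

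The labels do not say that the arrays hold different RNA pools, so the pair was treated as 1 replicate measured with both dye orientations. No test of the populations is possible with 1 replicate. A gene was called by a rule of size, namely a mean log2 ratio of at least 1 (2-fold) and a ratio of at least 0.5 in the same direction on each array. Turning the sign of array 2 and applying the same rule gives a count from dye bias and noise, which can be too low because genes that differ between the populations then seldom pass. As an alternative, limma's lmFit and eBayes were run on the 2 arrays with Benjamini-Hochberg adjustment. A gene was called by limma at an adjusted p under 0.05 with the same 2-fold minimum of the mean ratio. Its p-values measure only the spread between hybridisations, which may be technical. SDs given below are over the same 2 arrays and carry no animal-to-animal spread. The 2 arrays were scanned on the same day from 1 slide, so slide and scan day could not differ between the populations.

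A probe not well above background for 1 population on both arrays has only a bound there, given as "at least" a fold. The bound sets the bright population's mean log2 level, after loess and a scaling of mean intensities between arrays (Aquantile), against the higher of the dim probe's own level and the lowest level among probes well above background, per array. Where the dim probe's own level was the higher on both arrays, as for Ly6a, Defb6 and Krt1, the bound equals the measured fold. It makes no allowance for noise and is not a confidence limit. Ratios of dim genes are also compressed by the offset of 50.

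The design, the alternatives apart from those named below as added, 25 gene lists and the rule for named genes were fixed before the data were examined. The rule names Lgr5 and Lgr6; 10 genes chosen for their place in skin biology; the 12 largest mean log2 ratios in each direction among called genes measured in both populations on both arrays; the 4 largest bounds in each direction; and per list up to 4 called members of largest size, or 2 members where none was called. Clone, predicted and accession names were left out of the largest ratios and bounds. Other genes named below were chosen after their values were seen. Each list with at least 5 measured genes was described by its median mean log2 ratio among the medians of 10000 random lists of the same size matched on mean intensity in 10 bins. A list is called outside the random range when its median lies outside the central 95%. This percentile describes these 2 arrays and is not a p-value.

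The calling step was tested on simulated data. Noise drawn from the difference between the arrays was given to the 6195 genes, and 50 genes per fold size received a known fold for the comparison of Lgr6-high with Lgr5-high. The rule recovered 3 of 50 genes at 1.5-fold, 29 of 50 at 2-fold, 47 of 50 at 3-fold and 49 of 50 at 5-fold, and called 61 of 5995 unchanged genes. With limma, 31 of the unchanged genes were called. The simulated noise was independent between the arrays. Variation shared by both arrays, as between sorts or animals, was absent from it, and dye bias of single genes entered as noise. Alternatives covered the background correction and its offset, normalisation, filters on dim and saturated spots, the choice of probe, size thresholds, each array alone, limma, the scanner's p-values and the authors' value table. Added after seeing the data were the default background fit, the fit without the 1 spot, and leaving out the 1% of genes with the highest intensity. Work used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.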

Results

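RNA of dorsal skin cells with a bright Lgr6 reporter was compared with RNA of dorsal skin cells with a bright Lgr5 reporter on 2 arrays, 1 per dye orientation. Each array carried both populations, so that n = 2 arrays for each ratio, and the labels do not say whether the arrays held independent RNA pools. Cy3 signals were well above background at 31.6% and 33.3% of probe spots on arrays 1 and 2, and Cy5 signals at 15.3% and 16.2%. The median Cy3 signal was 99.8 and 102, against 92.8 and 91.9 at negative controls, and the median Cy5 signal 156 and 155, against 153 and 152. Values below are mean log2 ratios of Lgr6-high over Lgr5-high ± SD of the 2 arrays, positive where the Lgr6-high cells had more.

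The comparison asked which genes distinguished the Lgr6-high from the Lgr5-high cells. Markers of the upper follicle (5 of 11 measured) and of suprabasal epidermis (5 of 11) were higher in the Lgr6-high cells, and markers of the bulge (5 of 12), the cell cycle (12 of 27) and dermal fibroblasts (5 of 8) in the Lgr5-high cells. The largest single ratios toward Lgr6-high cells included Ly6d, a surface protein of epithelial cells (4.94 ± 0.79), the metalloprotease gene Adam8 (4.94 ± 0.37), the protease inhibitor Cst6 (3.96 ± 0.48) and Igfbp3, a binding protein of insulin-like growth factors (3.85 ± 0.05). Toward Lgr5-high cells they included the T-box factor Tbx1 (-3.33 ± 0.20), the smooth muscle myosin light chain Myl9 (-3.65 ± 0.98), the galectin Lgals1 (-3.58 ± 0.20), the glycine methyltransferase Gnmt (-3.16 ± 0.70), the calcium channel Trpv4 (-2.68 ± 0.19) and the microtubule regulator Stmn1 (-2.25 ± 0.38).

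Other large values for Lgr6-high cells came from Fcgbp (4.28 ± 0.59), the calmodulin-like Calm4 (3.17 ± 0.13) and Tnfaip3, an inhibitor of NF-kappaB signalling (3.09 ± 0.33). For 4 more genes the Lgr5-high signal was at background on both arrays. Ch25h, the cholesterol 25-hydroxylase, was at least 34.6-fold higher, the defensin Defb6 at least 7.66-fold, the cytokine Il33 at least 6.92-fold and Clca3a2 at least 6.64-fold. On the Lgr5-high side stood the tubulin Tubb5 (-2.41 ± 0.79), the aminopeptidase Lap3 (-2.35 ± 0.22) and the growth factor binding protein Igfbp7 (-2.27 ± 0.15). The histone H2ac1 (-2.24 ± 1.30) and the LIM protein Crip1 (-2.17 ± 1.23) were smaller on array 1 alone, at -1.33 and -1.31. The inner root sheath keratin Krt28 was at least 5.73-fold higher in Lgr5-high cells, and the melanin synthesis enzyme Dct at least 2.94-fold.

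Of 6195 genes, 451 were called higher in Lgr6-high and 295 in Lgr5-high cells, together 12.04%. Of these, 109 and 31 differed at least 4-fold. In 36 and 14 of the called genes the other population was at background on both arrays. With array 2's sign turned, 31 genes passed the same rule, 4.16% of the called number, while in simulated noise the rule called 61 of 5995 unchanged genes. The simulation held no variation shared by both arrays, so 61 is not an estimate of false calls between the populations. Limma, with the same 2-fold minimum, called 458 and 302 genes, among them all 451 and 295. The shared minimum makes much of this overlap by construction. With the turned sign it called 0, and 14 genes at least 2-fold had an unadjusted p under 0.05. That 0 does not estimate false calls, since turning moves real differences into limma's residual spread, and limma called 31 of 5995 unchanged genes in simulated noise. The 2 arrays' ratios correlated at a Pearson r of 0.749 and a Spearman rho of 0.650 across genes, which are not independent replicates. The ratios had the same sign for 72.5% of genes, and the median SD was 0.23. The split between directions depended on scaling. It was 957 and 959 with the scanner's ratios, 212 and 204 without background subtraction, 134 and 57 with median centring and no loess, and 124 and 151 with marked outlier spots kept in the background fit. From array 2 alone 611 and 471 genes passed 2-fold, and from array 1 alone 434 and 315.

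**Figure D1:**
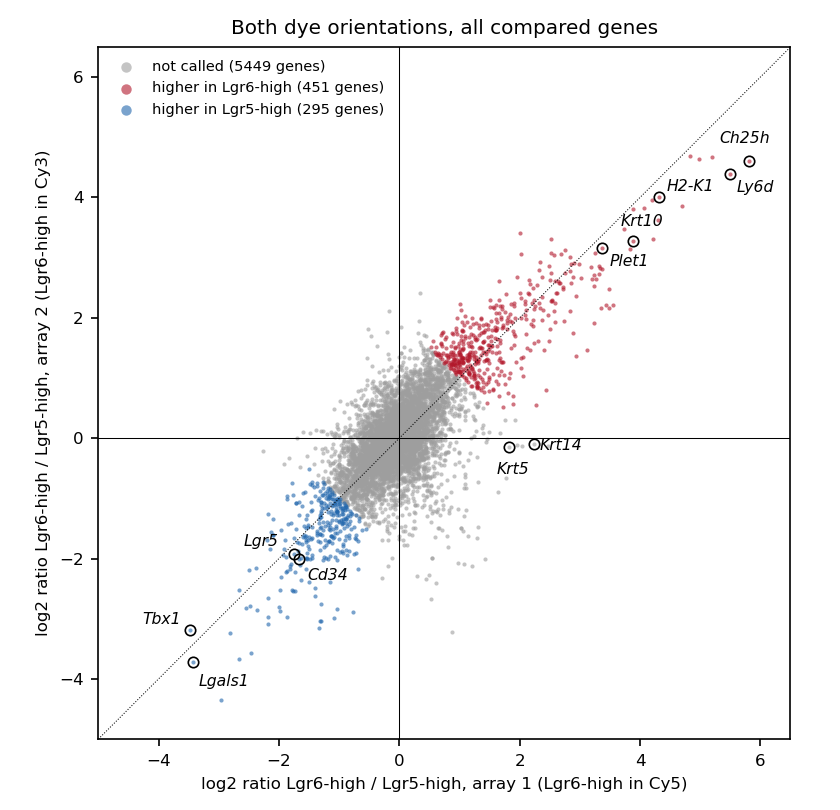
Log2 ratio of Lgr6-high over Lgr5-high on array 1 (x axis) against array 2 (y axis), 1 point per gene, with genes called in each direction in colour and selected genes named. The 451 genes called higher in Lgr6-high cells lie at the upper right and the 295 called higher in Lgr5-high cells at the lower left, and the Pearson r across all 6195 genes was 0.749.

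The genes whose reporters defined the sorts were read first. Lgr5, a receptor of follicle stem cells, was lower in the Lgr6-high cells (-1.83 ± 0.12), where its probe at mm9 chromosome 10, 114888847 to 114888906, was above background on 1 of 2 arrays. The scanner's own ratio for this probe was -4.26, and without background subtraction it was -1.19. A second Lgr5 probe was at background in both populations on both arrays, at 0.07 ± 0.04. The brighter of the Lgr6 probes, at mm9 chromosome 1, 136880538 to 136880597, was above background only in the Lgr6-high cells on array 2. Its ratio was 0.05 ± 0.14, so that Lgr6 did not enter the comparison, and the Lgr6-high label could not be checked by its own transcript.

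Bulge and hair germ markers lay on the Lgr5-high side. Of 12 measured genes 5 were higher in Lgr5-high cells and none in Lgr6-high cells. Besides Lgr5 and Tbx1 these were the surface sialomucin Cd34 (-1.84 ± 0.23), the homeobox factor Lhx2 (-2.13 ± 0.24) and the Wnt pathway repressor Tcf7l1 (-1.26 ± 0.07), which was above background in Lgr6-high cells on 1 array. Sox9 (-0.23 ± 0.39) and the keratin Krt15 (0.91 ± 1.46) were not called. The list's median of -0.72 stood at percentile 0.13 of intensity-matched random lists. Dermal fibroblast markers were higher in the same cells, with a list median of -1.76.

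Markers of the isthmus and infundibulum, the upper follicle, lay on the Lgr6-high side. Of 11 measured genes 5 were higher there. They were Cst6, Defb6, the upper follicle antigen Plet1 (3.26 ± 0.15), the transcription factor Klf5 (2.40 ± 0.17) and the keratin Krt79 (1.85 ± 0.23). Sostdc1, an inhibitor of BMP and Wnt signalling, was higher in Lgr5-high cells (-2.15 ± 0.52). The growth inhibitor Lrig1 had a ratio of -0.01 ± 0.10. Ly6a had 0.56 ± 0.02 (1.47-fold) with Lgr5-high cells at background and was not called. With the scanner's ratios it was 2.95 and called. Prdm1 was too dim to compare. The list's median of 0.77 stood at percentile 99.9.

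Interfollicular basal and suprabasal genes were higher in the Lgr6-high cells too. Among 16 basal genes 6 were called, including the matrix protein Thbs1 (2.12 ± 0.02), the hemidesmosome collagen Col17a1 (1.67 ± 0.48) and the integrin Itga6 (1.58 ± 0.36), while the growth factor Ptn was higher in Lgr5-high cells (-1.41 ± 0.63). The metal-binding Mt2 was 2.28 on array 1 and 0.55 on array 2, and -0.052 on average with marked outlier spots kept. Its scanner's ratios were 1.59 and 1.77 on arrays 1 and 2. The basal keratins Krt5 (0.83 ± 1.39) and Krt14 (1.07 ± 1.65) were not called, since on array 2 they measured -0.15 and -0.10. On array 1 they measured 1.82 and 2.24 and Krt15 1.95, and the scanner's ratios called all 3, at 1.12, 1.35 and 1.27. The scanner's ratios of Krt5, Krt14 and Krt15 were 1.07, 1.65 and 1.43 on array 1 and 1.17, 1.06 and 1.11 on array 2. After loess, the 1% of genes with the highest intensity had medians of 0.64 and -1.35 on arrays 1 and 2. Loess-normalised values of very bright genes on 1 array are therefore less certain. The basal median of 0.89 exceeded all 10000 random medians, and it was 0.55 on array 2 alone. Among 11 suprabasal genes 5 were higher, namely the keratins Krt10 (3.58 ± 0.43) and Krt1 (at least 4.68-fold), the cornified envelope genes Sprr1a (2.51 ± 0.14) and Lor (2.08 ± 0.43), and the transcription factor Klf4 (1.67 ± 0.25). Lor was above background in Lgr5-high cells on 1 array, and the suprabasal median was 0.93 (percentile 99.98).

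Hair lineage genes split. Of 10 measured matrix, inner root sheath and hair shaft genes 3 were higher in Lgr6-high cells, namely the epidermal differentiation factor Ovol1 (3.49 ± 0.50), the stress keratin Krt16 (2.97 ± 0.37) and the transcription factor Gata3 (2.56 ± 0.33). The other 3 called genes, higher in Lgr5-high cells, were the sheath and companion layer keratins Krt28 (at least 5.73-fold), Krt71 (-1.76 ± 0.33) and Krt75 (-1.34 ± 0.24), the last pair above background in Lgr6-high cells on 1 array. The list's median was -0.53 (percentile 0.55) and its mean 0.14, of opposite sign. The median lay inside the random range without background subtraction (-0.27) and without the filter on dim probes (-0.05). In the sebaceous and lipid list 2 of 9 measured genes were higher in Lgr6-high cells, including the lipid droplet protein Cidea (1.05 ± 0.16, Lgr5-high above background on 1 array, not called from array 1 alone at 0.94). That list's median of 0.40 (percentile 97.9) was inside the random range from array 2 alone (0.24), with the scanner's ratios or the authors' value table (0.75), with both populations above background (0.54) and against random lists not matched on intensity.

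Signalling genes moved in both directions. Wnt10a (2.37 ± 0.28), Wnt3 (2.02 and 1.99 on arrays 1 and 2, Lgr5-high above background on 1 array) and the growth regulator Myc (1.18 ± 0.22) were higher in Lgr6-high cells. The Wnt receptors Fzd2 (-1.31 ± 0.18) and Fzd1 (-1.16 ± 0.07), the cyclin Ccnd1 (-1.30 ± 0.29) and the Wnt antagonist Sfrp1 (-1.01 ± 0.01) were higher in Lgr5-high cells, with Fzd1 and Sfrp1 above background in Lgr6-high cells on 1 array. The median of the 14 Wnt genes was 0.55 (percentile 99.9), 0.33 on array 1 alone, and 0.06 and inside the random range without the filter on dim probes. The growth factor Epgn (1.91 ± 0.46), the MAPK feedback inhibitor Spry1 (1.91 ± 0.05, Lgr5-high above background on 1 array) and the EGF receptor inhibitor Errfi1 (1.51 ± 0.47) were the 3 called genes of 9 in the EGF receptor list, all higher in Lgr6-high cells. Its median was 0.68 (percentile 99.2) and inside the random range from array 2 alone, at 0.60, and without the filter on dim probes, at 0.082.

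Of 12 measured BMP and TGF-beta genes (28 on the array), Fstl1 (-1.38 ± 0.34) and the BMP target Id4 (-1.16 ± 0.11) were higher in Lgr5-high cells, each above background in Lgr6-high cells on 1 array. Both lost the call without background subtraction, at -0.87 and -0.81. The list median was -0.05 (percentile 44.3). None of 5 measured Notch genes (21 on the array) was called, the ligands Dll1 and Jag2 having 0.75 ± 0.33 and 0.59 ± 0.54, with a median of 0.46 (percentile 96.3). Dll1 was called with the scanner's ratios, at 1.98. Of 4 measured Hedgehog genes the cyclin Ccnd2 was higher in Lgr6-high cells (1.66 ± 0.18), and the median of -0.03 and mean of 0.23 differed in sign. Among 15 Eph, ephrin and axon guidance genes the ephrin Efnb2 (1.36 ± 0.48) was higher in Lgr6-high cells and the neuropilin Nrp2 (-1.06 ± 0.07, Lgr6-high above background on 1 array) in Lgr5-high cells. Their median was 0.01 and mean -0.01 (percentile 64.7).

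Cell cycle genes were higher in the Lgr5-high cells and immediate early genes in the Lgr6-high cells. Of 27 cell cycle genes 12 were higher in Lgr5-high cells, among them the mitotic regulators Birc5 (-1.73 ± 0.38) and Ccnb2 (-1.62 ± 0.09) and the replication helicase subunit Mcm7 (-1.64 ± 0.11). The cell cycle inhibitor Cdkn1a was the 1 gene higher in Lgr6-high cells (1.64 ± 0.02). The list's median of -0.88 was below all 10000 random medians. Of 24 immediate early and stress genes 17 were higher in Lgr6-high cells and none in Lgr5-high cells, with a median of 1.59 above all random medians. Examples were the phosphatase Dusp1 (3.09 ± 0.40), the nuclear receptor Nr4a1 (2.82 ± 0.93), the transcription factor Atf3 (2.82 ± 0.86) and the antiproliferative Btg2 (2.63 ± 0.07). The 5 heat shock genes of this list had medians of 1.29 on array 1 and -0.32 on array 2. The brightest Klf2 probe had -0.01 and another 2.96.

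Antigen presentation genes were higher in the Lgr6-high cells. Of 11 measured genes 8 were higher there and none in Lgr5-high cells, including the class I heavy chains H2-K1 (4.17 ± 0.22), H2-D1 (2.92 ± 0.40) and H2-Q7 (2.84 ± 0.25) and their light chain B2m (2.63 ± 0.16). The median of 1.45 exceeded all 10000 random medians. Class I genes are close paralogs, so that values of single members are less certain than the direction of the group.

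Matrix genes went both ways. The anchoring fibril collagen Col7a1 (1.94 ± 0.67), the laminin chain Lamb3 (1.16 ± 0.38) and Col16a1 (1.58 ± 0.78, with 1.02 on array 1) were higher in Lgr6-high cells. Col4a1 (-2.01 ± 0.87, Lgr6-high above background on 1 array), Hspg2 (-1.63 ± 0.30), Col18a1 (-1.57 ± 0.09) and Col4a2 (-1.08 ± 0.40) were higher in Lgr5-high cells. The 14 measured genes had a median of -0.25 (percentile 13.2).

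Markers of other skin cell types were also unequal. Of 8 measured fibroblast markers (18 on the array) 5 were higher in Lgr5-high cells, including the fibrillar collagens Col1a2 (-2.63 ± 0.22), Col1a1 (-2.61 ± 0.34) and Col3a1 (at least 5.28-fold) and the proteoglycan Dcn (at least 4.14-fold). Their median of -1.76 was below all 10000 random medians, and with genes at background set to their bound it was -1.71. The first pair was above background in Lgr6-high cells on 1 array. Of 19 endothelial and mural markers on the array only 4 were measured. Of these 4, 3 were higher in Lgr5-high cells, namely the actin-binding Tagln (-3.02 ± 0.78), Ramp2 (-2.42 ± 0.33, Lgr6-high above background on 1 array) and Egfl7 (at least 2.19-fold, not called from array 1 alone at -0.93), while Acta2 had 0.90 ± 0.42. The haemoglobin genes Hbb-bt (-1.60 ± 0.01) and Hba-a1 (-1.13 ± 0.42, not called from array 1 alone at -0.83), the 2 measured genes of the muscle, adipocyte and red cell list, were higher in Lgr5-high cells. Dct was the 1 melanocyte marker measured, and none of 17 dermal papilla markers was.

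The Schwann cell and nerve list differed from these. Its 3 measured genes, the myelin genes Pmp22 (2.60 ± 0.17) and Mbp (1.85 ± 0.10, Lgr5-high above background on 1 array) and the neurotrophin receptor Ngfr (1.42 ± 0.02), were higher in Lgr6-high cells. Mbp was measured by 1 probe, and its other probes were at background in both populations on both arrays. Neither of the 2 measured leukocyte markers, Thy1 (-0.17 ± 0.34) and Epcam (0.14 ± 0.16), was called. None of the 3 measured Merkel cell genes was called either, with Krt18 at -0.46 ± 0.19 and Tubb3 at 0.27 ± 0.32. Krt18 was called with the scanner's ratios, at -1.04.

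Of 7 sex-linked genes 1 entered the comparison. Xist, the RNA of the inactive X chromosome, was at least 2.60-fold higher in Lgr5-high cells and at background in Lgr6-high cells. It lost the call without background subtraction, at -0.88. The Y-linked Ddx3y (0.40 ± 0.46) and Eif2s3y (0.56 ± 0.42) were above background only in Lgr6-high cells on array 2. The labels do not give the sex of the mice, so a difference in sex between the pools stays open for the whole comparison. Of 178 genes on chromosome X, 8 were higher in Lgr6-high and 10 in Lgr5-high cells.

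Of 16 lists with at least 5 measured genes, 12 lay outside the random range, 8 toward Lgr6-high and 4 toward Lgr5-high cells. For genes drawn at random 0.8 would lie outside. Members of a list can vary together and some lists share members, so 0.8 is not a rate of false lists. Limma's counts adjusted over the list alone equalled those over all genes tested, except for the upper follicle list (2 in place of 1 higher in Lgr5-high cells) and the basal list (7 in place of 6 higher in Lgr6-high cells). With only the dye-swapped pair, neither the lists nor single genes could be tested against animal-to-animal variation.

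**Figure D2:**
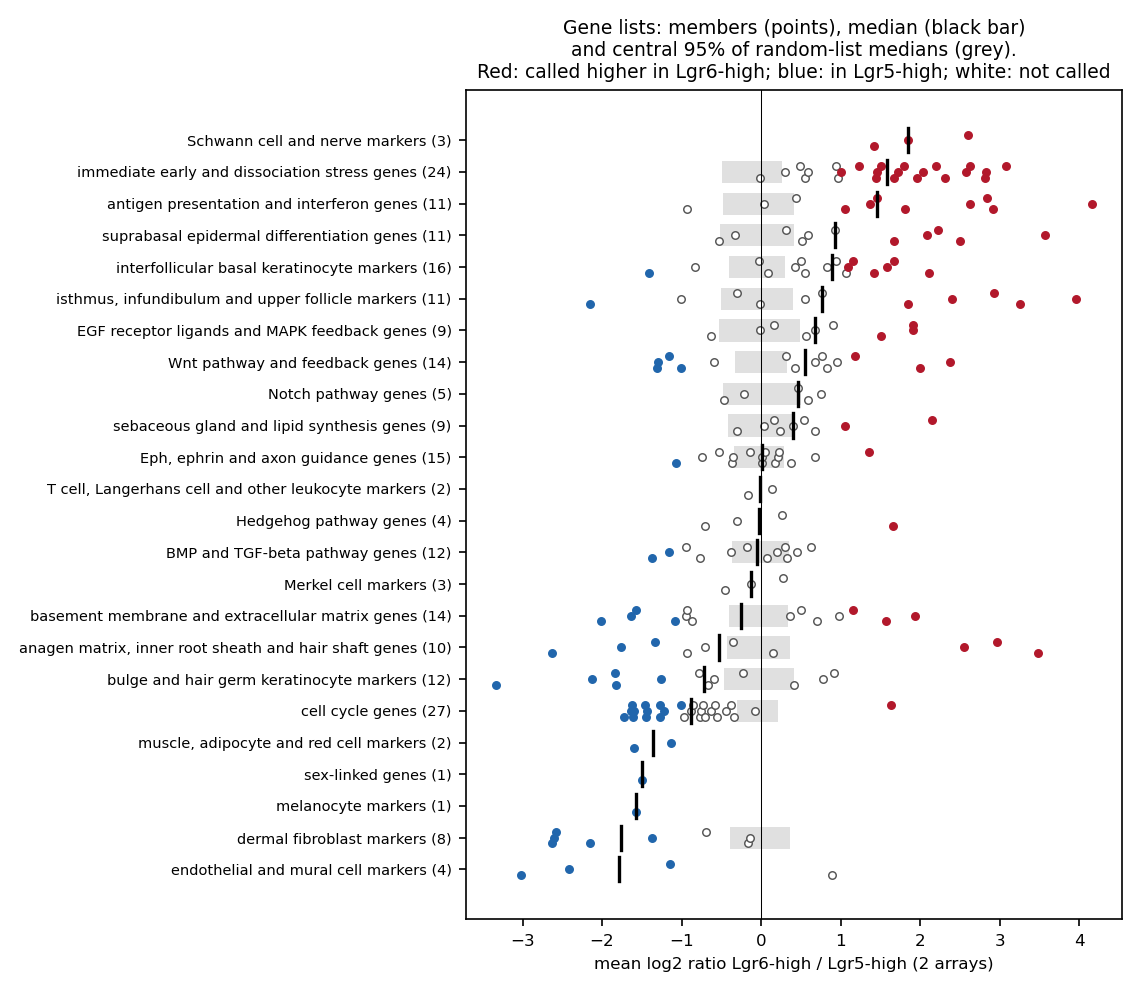
Mean log2 ratio of Lgr6-high over Lgr5-high (x axis) of each measured member of each fixed list (1 point per gene), with the list's median as a bar and, for lists with at least 5 measured genes, the central 95% of random-list medians in grey. The medians of the cell cycle list (-0.88) and the immediate early list (1.59) lie outside the range of random medians on opposite sides.

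**Figure D3:**
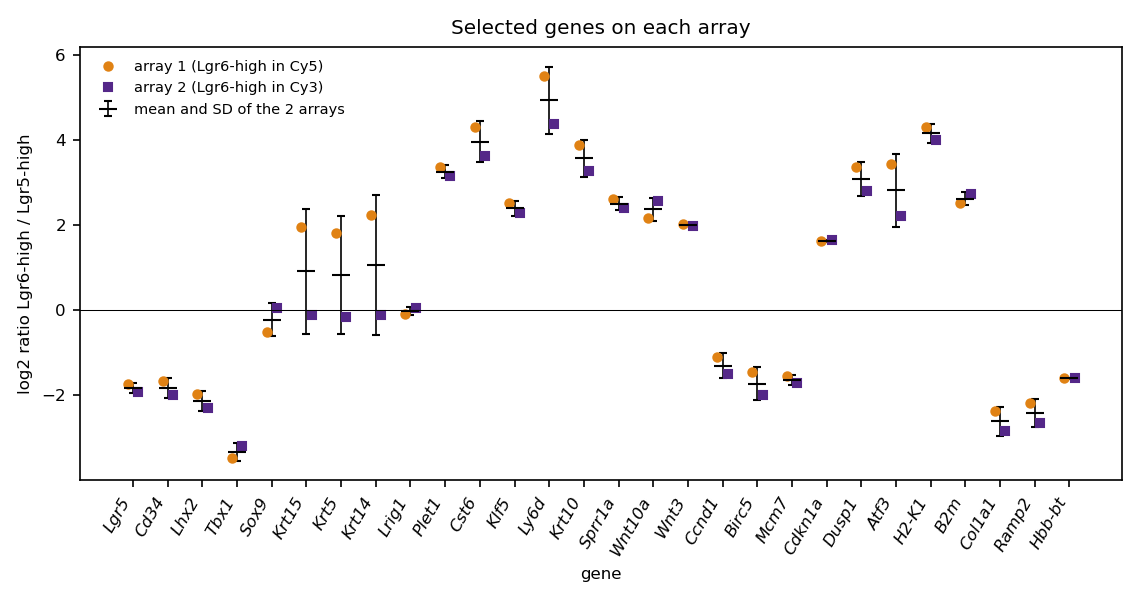
Log2 ratio of Lgr6-high over Lgr5-high of selected genes (y axis) of selected genes (x axis) on each of the 2 arrays, with their mean and SD. Tbx1 and Lhx2 lie below 0 and Plet1 and H2-K1 above 0 on both arrays, whereas Krt14 was 2.24 on array 1 and -0.10 on array 2.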

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

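The values here were chosen after they were seen, and no test was run on them. Control probes for adenovirus E1A transcripts, which serve as added RNA controls on this type of array, gave a signal outside the gene comparison. Of 10 such control probes with 32 spots each, 8 were above background in both dyes on both arrays (8 on array 1 and 10 on array 2), while 0 of 153 negative control spots were. Their log2 ratios of Cy5 over Cy3 ranged from -3.29 to 3.12 on array 1 and from -2.70 to 3.59 on array 2, with a Pearson r of 0.985 across probes. The ratio was higher on array 2 for 10 of 10 probes, by a median of 0.74 (range 0.47 to 1.55).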

How the results depend on the processing

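Alternatives were planned apart from the background fits with outlier spots kept or with 1 spot left out and the comparison without the 1% brightest genes. No called gene was called in the opposite direction under any normalisation, filter or probe choice tried. Of the 746 called genes 730 kept their call with the scanner's ratios, 726 with offset 16, 687 with the mean over probes, 391 without background subtraction, 236 with outlier spots kept and 174 with median centring. Named genes that lost the call with median centring kept mean ratios of at least 2-fold, such as Cd34 (-1.82) and Gata3 (2.67), and failed the rule on single arrays. Medians of lists outside the random range stayed outside in 180 recomputed values and fell inside in 10 (sebaceous, hair lineage, Wnt and EGF receptor lists), none changing direction. Those of lists inside it stayed inside in 62 and moved outside in 1 (Notch with offset 16). Called named genes kept their call in 1226 recomputed values and lost it in 77, and uncalled ones stayed uncalled in 183 and gained a call in 19. These tallies include settings that could not change a ratio, namely Aquantile and leaving out saturated spots. They also count the scanner's ratios again as the authors' value table. Mt2 reversed to -0.052 with outlier spots kept.

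Without background subtraction 212 genes were higher in Lgr6-high cells, 108 passed with array 2 turned, r was 0.457 and Lgr5 -1.19. Offset 16 gave 685 genes, 13 turned, r 0.787 and Lgr5 -2.52. The scanner's ratios and the authors' value table, which hold the same values, gave 957 and 959 genes, r 0.844, Lgr5 -4.26 and Lgr6 0.32. A larger offset, or no subtraction, compresses the ratios of dim spots by construction. Median centring gave 134 and 57 genes, 4348 turned, r 0.323 and Lgr6 0.26. The array medians of compared genes then lay at -1.36 and 1.57, an intensity-dependent dye effect, against -0.04 and -0.02 after loess. Outlier spots kept gave 124 and 151 genes, 94 turned, r 0.231 and Lgr5 -1.01. This came from 1 spot on array 2, since leaving out that spot alone gave 450 and 292 genes, 31 turned and r 0.749, with 742 of the 746 calls kept. Pearson r was 0.605 without a filter on dim probes and 0.716 with both populations above background; the mean over probes gave 20 turned genes. The cause was not tested for these. Among the 1% brightest genes loess left medians of 0.64 on array 1 and -1.35 on array 2, each toward Cy5. Without these genes, whose median SD was 1.41, 6 turned genes and an r of 0.783 were left.

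A size minimum of 0.58 gave 759 and 712 genes and 88 turned, and a minimum of 2 gave 109, 31 and 1, by construction. At least 1 on each array gave 194 genes higher in Lgr5-high cells and 11 turned, limma 0 turned (real differences then count as residual spread), and the scanner's p 3 turned. Leaving out an array gave 315 to 471 genes higher in Lgr5-high cells. Low Cy5 signal over background limits the genes compared, and a gene dim in both populations, such as Lgr6, stays unmeasured.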

Other observations

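All tests here were chosen after the results were seen, except that of chromosome segments. Families of at least 8 genes sharing the start of their symbol, and the single genes named below, were likewise chosen after seeing the data. Histone genes were higher in Lgr5-high cells in 14 of 27 measured cases and in Lgr6-high cells in 1, with a median of -1.02. Their probes were not checked for cross-hybridisation within the family. The nucleotide synthesis genes Tk1 (-1.98 ± 0.35) and Dut (-1.78 ± 0.31) and the methyl cycle enzymes Ahcy (-2.05 ± 0.24) and Sardh (-1.99 ± 0.25, Lgr6-high above background on 1 array) were higher in Lgr5-high cells too. Mitochondrial ribosomal genes of the large subunit had a median of -0.43 (41 measured, 4 higher in Lgr5-high cells), and the Ndufa genes of respiratory complex I -0.63 (13 measured, 1 higher in Lgr5-high cells). These medians kept their sign under the 5 other scalings tried. Of 71 families, 18 lay outside the random range, 8 toward Lgr6-high and 10 toward Lgr5-high cells. For genes drawn at random 3.55 would, and genes of a family can vary together.

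Single genes with large ratios toward Lgr6-high cells, picked by their values and not tested as a group, included the following. The serpin Serpinb2 (4.81 ± 0.24, Lgr5-high above background on 1 array), the cytokine Tslp (at least 6.55-fold, Lgr5-high at background), the chemokines Cxcl16 (2.65 ± 0.40) and Ccl27a (2.62 ± 0.05) and the NF-kappaB regulators Bcl3 (2.93 ± 0.13) and Nfkbiz (2.14 ± 0.68) were called. So were the tight junction gene Cldn1 (2.36 ± 0.01) and the cadherin Cdh1 (1.84 ± 0.48). Of 9 Klf transcription factors 4 were higher in Lgr6-high cells, with a median of 0.97. The 18 measured keratins had a median of 0.49, with 5 higher in Lgr6-high and 3 in Lgr5-high cells, and the median turned sign on array 2 alone (-0.14) and with outlier spots kept in the background fit (-0.28).

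Class I genes and Ifi202b, an interferon-induced gene, were higher in Lgr6-high cells (12 of 13 class I genes, median 2.81; Ifi202b 4.76 ± 0.09, Lgr5-high above background on 1 array). RNA from leukocytes would bring other leukocyte transcripts. Epcam and Thy1, above background in both populations, were left out of this count, a choice made after the data were seen. Of the 23 other markers, 0 were above background in Lgr6-high cells on both arrays and 1 on at least 1 array. In Lgr5-high cells 0 were above background on both arrays too. The Lgr6-high cells were read in Cy5 on array 1, where 15.3% of probe spots were well above background. The count, from a set chosen in this way, therefore cannot exclude leukocyte RNA. Cross-hybridisation among class I probes would not raise the 5 measured processing partners outside that family. These had a median of 1.37, 4 of them called, from Tap1 (0.04) to B2m (2.63). Their values were known before the test. They do not exclude cross-hybridisation among class I probes, nor show which single class I genes differ. Segments carried along with the knock-in alleles could raise the share of called genes within 20 Mb of the loci. There 17 of 124 were called (13.7%, Clopper-Pearson 95% interval 8.19 to 21.0), against 12.02% of 6041 genes elsewhere. Ifi202b lies on chromosome 1, as Lgr6 does, but at 175892953, beyond this window, and H2-K1, H2-D1 and H2-Q7 lie on chromosome 17. The partners Tap1, Tapbp, Psmb8 and Psmb9 lie on chromosome 17 too, so they are not independent of a segment there, and B2m lies on chromosome 2. The share therefore cannot decide whether a carried segment accounts for Ifi202b. A strain difference, in a carried segment or elsewhere in the genome, and a difference between the populations may each account for the pattern. No test here separates these.

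Immediate early genes were higher in Lgr6-high cells, and a difference in how the sorts were handled could raise them. The 5 heat shock genes of that list, which handling would be likely to raise as well, had a median of 0.56, with 2 called, and went apart between arrays (1.29 and -0.32). Their median was 0.06 without background subtraction, 0.87 with offset 16 and 0.80 with the scanner's ratios. Without them, 15 of 19 genes were called and the median was 1.79. Handling and a difference between the populations cannot be told apart, since the labels do not record the handling of each sort and the arrays differ on the genes that would decide.

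Of 15 measured fibroblast, vascular, melanocyte and red cell markers, 11 were higher in Lgr5-high cells and 0 in Lgr6-high cells. The 4 lists held 18, 19, 15 and 17 markers on the array, of which only 8, 4, 1 and 2 were measured. Some, such as Col3a1, Dcn, Dct and Egfl7, entered the comparison only through their Lgr5-high signal. Acta2 had 0.90, and Dct was the 1 melanocyte marker. The 3 measured genes of the Schwann cell and nerve list, Mbp by 1 probe only, were higher in Lgr6-high cells. The sort for bright reporter cells would remove cells without the reporter, and how far it did was not measured. The abundant fibroblast gene Vim was near background (-0.30 ± 0.24 by its brighter probe, above background in Lgr5-high cells on 1 array), which decides nothing from 1 gene. RNA from dermal and blood cells in the Lgr5-high sort and expression of these genes by the Lgr5-high cells themselves cannot be told apart, since the 11 markers are the ones that show the pattern.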
